A study of Mus musculus with 8 samples.

How the data were processed

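Total RNA of brown adipose tissue from 8 mice, 4 controls and 4 knockouts, had been extracted with Trizol and sequenced on an Illumina instrument, per the labels' protocols. Reads were aligned to mm10 with TopHat version 2, per the submitters' processing notes, which also name HOMER, edgeR and DESeq 1.8.3. The estimated counts deposited by the authors were made with HOMER's analyzeRepeats.pl from RefSeq gene models, with unadjusted counts over exons on both strands, per the file headers. Because strand was not used, reads of overlapping or antisense genes cannot be told apart. The deposited counts are multiples of 0.5, and 36.9% of the values are not whole, so they were rounded to whole numbers before testing. Transcript length in bases was given in the same table, per the file headers. A table of the authors' own comparison was also read. It holds counts scaled to equal totals, a signal made by the authors with a single factor per library. It also holds the authors' fold (ratio, knockout over control), the authors' p-value and FDR, and the authors' log2 fold change and log2 CPM, per the file headers. All columns of per-sample values could be matched to a library by the number in its title. The numbers differ between the groups, so no pairing was possible.

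The count table has 30521 rows, one per transcript. The 829 rows that name no gene symbol were left out, and they held 0.0608% to 0.0824% of the counts of a library. Where a symbol had several rows (3969 symbols), the row with the highest total over all libraries stood for the gene, which left 23372 genes and 23683798 to 28570446 counts per library. Summed over all rows, which count shared exons more than once, the libraries held 33011022 to 38756920 counts. Genes were kept by edgeR's filterByExpr with a minimum count of 10, leaving 14178. TMM factors were 0.898 to 0.961 in controls and 1.05 to 1.10 in knockouts. Genes were tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood test of knockout against control without covariates, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The common biological coefficient of variation was 0.181. The standard error given with a log2 fold change is its size divided by the square root of the test's F value, an approximation. CPM values are scaled by the TMM factors.

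Replicates were compared before averaging. The correlation of log2 CPM lay between 0.963 and 0.981 within controls, 0.985 and 0.991 within knockouts, and 0.942 and 0.972 between groups. The lowest chi-square per degree of freedom of a pair was 53.4 in controls and 13.1 in knockouts, so no pair agreed within sampling noise. The labels name no batch.

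There were 32 gene lists, fixed from textbook knowledge before the data were examined, of which 31 had at least 3 tested members. They cover brown thermogenic, white adipocyte enriched and pan-adipocyte genes, nuclear oxidative phosphorylation, mitochondrially encoded genes, the TCA cycle, mitochondrial and peroxisomal fatty acid oxidation, glycolysis and lactate, fatty acid and triglyceride synthesis, cholesterol synthesis, branched-chain amino acid catabolism, creatine and calcium cycling, and mitochondrial biogenesis and dynamics. Others cover the glucocorticoid response, LSD1 complexes and paralog, neuronal genes, the unfolded protein and integrated stress response, extracellular matrix and fibrosis, inflammation and interferon, the cell cycle, immediate early genes, the circadian clock and sex-linked genes. Markers of other cell types were those of fibroblasts and preadipocytes, macrophages, lymphocytes, endothelium, smooth muscle and pericytes, skeletal muscle, Schwann cells and nerve, and erythroid cells. Of the list entries 588 were matched by symbol, 1 by a RefSeq synonym and 16 were not matched. Lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2, a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists. The same test with an estimated correlation (median 0.183) and fry, which asks whether a list's genes move on balance in a single direction, were run beside it.

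The named genes followed a rule also fixed before the data were examined. They are Kdm1a and Ucp1, the 10 largest rises and 10 largest falls among called genes with a mean of at least 5 CPM and no overlap between the groups, up to 4 members of each list with the smallest p, and the 3 genes with the smallest p in each direction, leaving out uncharacterised gene models. The text gives a selection of the 144 genes so named, and says where another gene was picked out after its value was seen.

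Tests were checked on simulated counts with 50 changed genes per fold size among 14054 genes of a simulated knockout against control. The quasi-likelihood test recovered 0% of genes changed 1.25-fold, 22% at 1.5-fold, 62% at 2-fold and 94% at 4-fold, with 6 false calls. Alternatives were relative log expression factors, upper quartile factors and library sizes alone, no low-count filter and a filter of 1 CPM in 4 libraries, DESeq2 1.42.0, the edgeR exact test, limma-voom with and without sample weights, all transcript rows as deposited, each library left out in turn, stricter thresholds, and the other list tests. Added after the data were seen were a muscle score as a covariate, a correction of each library for transcript length and GC content with smooth curves, that correction without centring of the curves, and an exact permutation of list scores over the 35 splits of the libraries. In that permutation a list's score was taken relative to the mean of all tested genes. Coordinates are those of the count table, on mm10, counted from 1.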

Results

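Brown adipose tissue, the fat that burns fuel to make heat, was collected from 10-week-old mice, and its RNA was sequenced. The knockout mice carried floxed alleles of Lsd1, a histone demethylase whose gene symbol is Kdm1a, together with Cre recombinase driven by the Ucp1 promoter, which is active in brown adipocytes. The control mice were described as floxed only, so the loss of Lsd1 and the presence of the Cre transgene went together in this design. There were 4 control libraries (replicates 511, 514, 517 and 518) and 4 knockout libraries (replicates 512, 513, 515 and 516). The summed counts per library lay between 33011022 and 38756920. The comparison asks which transcripts of the tissue differ when Lsd1 is deleted in brown adipocytes. Levels are given below as CPM, counts scaled to a common library size, with the SD over the 4 libraries of a group, and log2 fold changes as knockout over control with an approximate standard error (SE). Adjusted p-values of genes are from edgeR's quasi-likelihood test, and those of gene lists from limma's camera. The labels give each library its own number but do not say more about how the mice were kept, so the p-values measure the spread between these samples.

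The targeted gene Kdm1a (chromosome 4, 136550533 to 136602723, minus strand, mm10) was lower in every knockout library. Its level was 35.4 ± 1.52 CPM (SD, n = 4) in controls and 13.1 ± 0.711 CPM (SD, n = 4) in knockouts, a log2 fold change of -1.43 (SE 0.0743, edgeR adjusted p = 2.66e-05). The control libraries held 35.3, 36.0, 33.3 and 36.9 CPM and the knockout libraries 14.0, 12.2, 13.2 and 13.0 CPM, in the order of the replicate numbers above. The counts cover all exons of the gene, so reads from the deleted part and from the rest of the transcript were not separated. Cells in which the Ucp1 promoter is silent keep the gene.

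Ucp1 itself, the uncoupling protein that lets brown fat mitochondria release heat (chromosome 8, 83290348 to 83298456, plus strand), fell from 4481 ± 1200 CPM (SD, n = 4) to 1377 ± 161 CPM (SD, n = 4). Its log2 fold change was -1.70 (SE 0.191, edgeR adjusted p = 0.000477). The largest fall among the genes singled out by size was that of Clstn3, calsyntenin 3, from 316.5 ± 33.1 to 47.3 ± 3.99 CPM, which is 6.68-fold lower (SE 0.0989 on the log2 scale, edgeR adjusted p = 2.36e-06). The Clstn3 row (chromosome 6, 124430756 to 124464784) may also hold reads of Clstn3b, a fat cell product of the same locus that the annotation lists as a synonym. Elmod2, a GTPase-activating protein encoded next to Ucp1 (chromosome 8, 83312632 to 83332486), rose 6.51-fold, from 45.1 ± 3.74 to 293.8 ± 16.7 CPM (SE 0.0826 on the log2 scale), and had the smallest edgeR adjusted p of all genes, 1.03e-06. The plot of counts per library shows all 4 genes with no overlap between the groups.

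**Figure D1:**
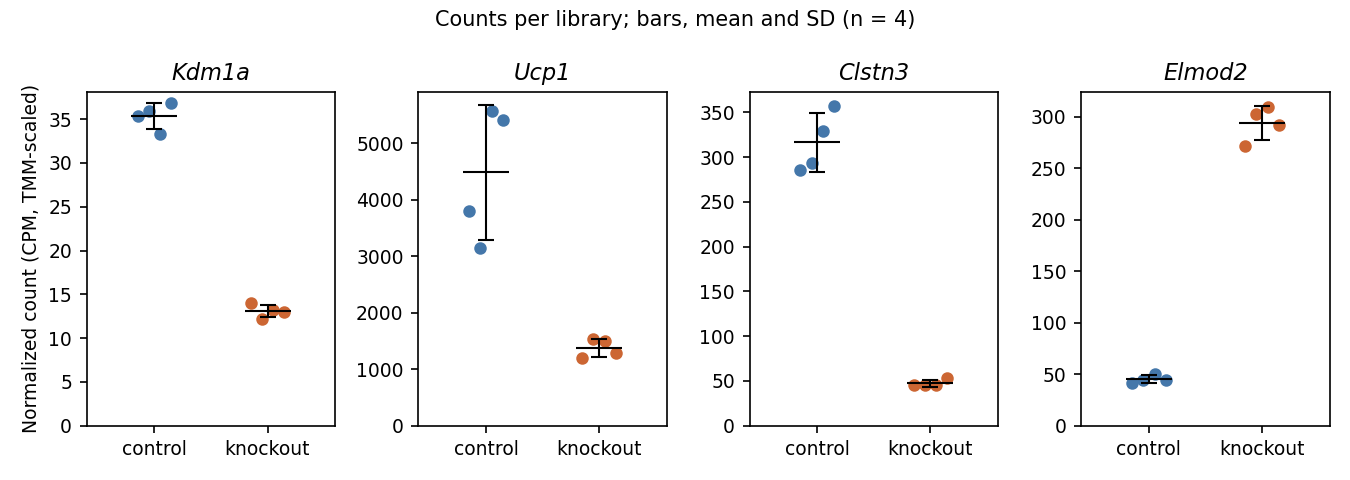
Normalised counts (CPM, linear axes from 0) of Kdm1a, Ucp1, Clstn3 and Elmod2 in the 4 control (blue) and 4 knockout (orange) libraries, one point per library, with the mean and SD in black. Kdm1a, Ucp1 and Clstn3 were lower and Elmod2 higher in all 4 knockout libraries.

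Of 14178 genes tested, 2189 were higher and 2682 lower in knockout tissue at an edgeR adjusted p under 0.05, together 34.4% of the genes. Large changes were mostly rises, with 844 genes at least 2-fold higher and 133 at least 2-fold lower. The values of the groups did not overlap for 4372 of the 4871 called genes, and for 35.5% of all tested genes, where chance gives 2.9%. The balance of directions depended on the scaling between libraries: upper quartile factors gave 2915 higher and 1625 lower genes, and library sizes alone 4077 higher and 930 lower. These scalings moved the median of all genes by 0.103 and 0.198 on the log2 scale. Under them and under relative log expression factors, the medians of the gene lists kept their sign except for the white adipocyte, glycolysis and LSD1 complex lists, named again below.

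The 10 largest rises were of genes with varied functions. Bdh1, a mitochondrial enzyme of ketone body metabolism, went from 0.561 ± 0.480 to 12.2 ± 0.935 CPM (log2 fold change 4.42, SE 0.425, edgeR adjusted p = 0.00027). Cend1, a neuronal differentiation protein, went from 2.50 ± 1.11 to 52.8 ± 5.82 CPM (log2 fold change 4.40, SE 0.255, edgeR adjusted p = 3.13e-05). Rises of 3.05 to 3.68 on the log2 scale were seen for the matrix protein gene Fras1 (3.68), the brain-type aldolase Aldoc (3.55), the orphan receptor Gpr162 (3.51), the neurotrypsin gene Prss12 (3.42), Rgs11, a regulator of G protein signalling (3.32), the glycosyltransferase gene Extl1 (3.24), Ndrg4 (3.15) and the ubiquitin ligase gene Rnf157 (3.05). Relative to their means, Fras1 and Extl1 varied most between knockout libraries, at 9.56 ± 5.12 and 31.6 ± 18.7 CPM. Tmem221, a membrane protein gene, and Paqr6, a membrane receptor gene, had smaller p-values than these, with log2 fold changes of 3.13 and 2.27 (edgeR adjusted p = 2.66e-05 for each).

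The largest falls after those of Clstn3 and Ucp1 included genes of lipid handling and others. Acot11, an acyl-CoA thioesterase of brown fat, fell by 1.70 on the log2 scale (edgeR adjusted p = 0.000495), Acsl5, an acyl-CoA synthetase, fell by 1.62, and Gyk, glycerol kinase, fell by 1.57. Also among the 10 largest falls were the DNA polymerase gene Poln, which fell by 1.70, the hydrolase gene Cmbl, which fell by 1.58, Nabp1, which fell by 1.62, and Ttc25, which fell by 1.61. Fam151a fell by 1.66, but 65.7% of its exon bases lie opposite Acot11, and counting without strand could not separate the pair.

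The fixed list of brown fat thermogenic genes was lower as a group. Of its 29 tested members, 17 were lower and 1 higher, and adjusted over the list alone 18 were lower and 1 higher (median log2 fold change -0.47, camera adjusted p = 3.26e-05). With an estimated correlation between genes the list did not pass (adjusted p = 0.202 with an estimated correlation). Of its members 13 were lower with library sizes alone, where the median was -0.275. Besides Ucp1, Acot11 and Gyk, the inner membrane protein gene Letmd1 fell from 985 ± 98.1 to 490 ± 19.4 CPM (log2 fold change -1.01, SE 0.0855), and the carnitine carrier gene Slc25a20 from 673 ± 48.6 to 425 ± 20.3 CPM. The single higher member, picked out after its value was seen, was Gmpr (0.44, edgeR adjusted p = 0.0404). Some regulators of the brown fat programme were called and others were not, and differences between them were not tested. The nuclear receptor gene Esrra fell by 0.47 (edgeR adjusted p = 0.00163), and, named after their values were seen, Prdm16 fell by 0.82 (0.0276) while Ppargc1a and Ebf2 had log2 fold changes of -0.03 (0.941) and -0.04 (0.934) and no call. Cidea, a lipid droplet gene of brown fat also named after its value was seen, had one of -0.26 (edgeR adjusted p = 0.0876).

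Genes shared by all fat cells were lower too. Of 19 tested, 10 were lower and 0 higher, and adjusted over the list alone 11 were lower (median log2 fold change -0.31, camera adjusted p = 0.00246, adjusted p = 0.226 with an estimated correlation). With upper quartile factors 5 were lower (median -0.209), and with library sizes alone 4 were lower and 1 higher (median -0.124). Gpd1, glycerol phosphate dehydrogenase, fell by 0.78 on the log2 scale, the lipase gene Mgll fell by 0.88, the fatty acid binding protein gene Fabp4 fell by 0.73 and the lipid droplet gene Cidec fell by 0.997. Adipoq, Plin1 and Plin4, named after their values were seen, had log2 fold changes of -0.17 (SE 0.0978), -0.21 (SE 0.0802) and -0.01 (SE 0.0967) and no call. Among 14 genes enriched in white over brown fat cells, 1 was higher and 1 lower, also when adjusted over the list alone. These were Nnat (log2 fold change 1.23) and the hormone gene Lep, leptin (-0.79, edgeR adjusted p = 0.0044). The call of Nnat ended without control 517, knockout 512 or knockout 515 (edgeR adjusted p = 0.0504, 0.0553 and 0.0585) and with the muscle score as a covariate, described below (0.119). By limma-voom with sample weights Nnat was not called either (log2 fold change 0.911, limma-voom adjusted p = 0.179). This list had a median of -0.000698, a mean of 0.0808 and an upward test (camera adjusted p = 0.81), and its median changed sign with each other scaling.

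Fuel oxidation genes were lower together. In mitochondrial fatty acid oxidation 20 of 21 tested genes were lower and 1 higher, with the same counts adjusted over the list alone (median log2 fold change -0.51, camera adjusted p = 1.66e-08, adjusted p = 0.202 with an estimated correlation). Hadha, a subunit of the trifunctional protein, fell from 3032 ± 209 to 1757 ± 77.9 CPM (log2 fold change -0.79, SE 0.0791, edgeR adjusted p = 0.000313). Cpt2, which regenerates acyl-CoA inside mitochondria, fell by 0.81, and Acsl1, an acyl-CoA synthetase, fell by 0.62. The higher member, picked out after its value was seen, was Cpt1a (0.53, edgeR adjusted p = 0.0405), the liver-type isoform of the enzyme for fatty acid entry. Peroxisomal fatty acid oxidation genes were lower in 12 of 16 cases and higher in 0, also adjusted over the list alone (median -0.48, camera adjusted p = 0.000178, adjusted p = 0.202 with an estimated correlation). With library sizes alone 12 mitochondrial genes were lower (median -0.314), and 7 peroxisomal genes were lower and 1 higher (median -0.277). Among the peroxisomal genes Hsd17b4, a multifunctional enzyme of peroxisomes, fell by 0.63.

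In the list of branched-chain amino acid breakdown, 16 of 20 genes were lower and 0 higher, and 19 were lower when adjusted over the list alone (median -0.59, camera adjusted p = 3.32e-08, adjusted p = 0.202 with an estimated correlation). The count lower with library sizes alone was 11 (median -0.394). Hibch, a hydrolase of valine breakdown, fell from 504 ± 33.0 to 327 ± 17.4 CPM, and Mccc1, a carboxylase of leucine breakdown, fell by 0.70 on the log2 scale. Bckdha fell by 0.62, but 61.7% of its exon bases lie opposite B3gnt8.

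Nuclear genes of oxidative phosphorylation showed small and broad falls, with 62 of 78 lower and 1 higher, and 67 lower and 2 higher adjusted over the list alone (median log2 fold change -0.35, camera adjusted p = 2.51e-15, adjusted p = 0.226 with an estimated correlation). Cox8b, a cytochrome c oxidase subunit, fell from 998 to 623 CPM (log2 fold change -0.68, SE 0.0822), Ndufab1 fell by 0.67 and Ndufb5 fell by 0.52. Ndufb6 fell by 0.52, with 39% of its exon bases opposite Smim27. The higher member, picked out after its value was seen, was Atp5g1, a subunit of ATP synthase (1.56, edgeR adjusted p = 0.0114), at 4.03 ± 1.92 CPM in controls. With library sizes alone the list's median was -0.151 and 23 genes were lower. For the TCA cycle 14 of 21 genes were lower and 0 higher, and 17 were lower adjusted over the list alone (median -0.40, camera adjusted p = 9.28e-07, adjusted p = 0.226 with an estimated correlation). Idh3a, a subunit of isocitrate dehydrogenase, fell by 0.55 and Sdhd, of succinate dehydrogenase, fell by 0.53. In mitochondrial biogenesis and dynamics 10 of 16 genes were lower and 0 higher, also adjusted over the list alone (median -0.25, camera adjusted p = 0.000372, adjusted p = 0.228 with an estimated correlation). Polrmt, the mitochondrial RNA polymerase gene, fell by 0.72 and Opa1, which fuses inner membranes, fell by 0.53. With library sizes alone 7 TCA cycle genes (median -0.20) and 4 biogenesis genes (median -0.051) were lower. Mitochondrially encoded genes were not analysed here.

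Lipid synthesis genes were also lower. In fatty acid and triglyceride synthesis 14 of 22 genes were lower and 2 higher, and 16 lower and 2 higher adjusted over the list alone (median -0.64, camera adjusted p = 0.00042, adjusted p = 0.274 with an estimated correlation). Agpat2, an acyltransferase of triglyceride synthesis, fell from 1034 ± 168 to 428 ± 79.0 CPM (log2 fold change -1.27, SE 0.156), and Thrsp, a lipogenic regulator, fell by 0.96. The fatty acid desaturases Fads1 and Fads2 went the other way and rose by 1.10 and 1.26, Fads2 being named after its value was seen. In cholesterol synthesis 14 of 23 genes were lower and 0 higher, also adjusted over the list alone (median -0.51, camera adjusted p = 0.000372, adjusted p = 0.389 with an estimated correlation). Lss, lanosterol synthase, fell by 0.65 and Nsdhl, a sterol dehydrogenase, fell by 1.02. In these lists 10 and 4 genes were lower with library sizes alone (medians -0.448 and -0.313).

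Glycolysis genes went both ways, with 7 of 22 lower and 4 higher, and 7 lower and 5 higher adjusted over the list alone. Hk1, a hexokinase, rose from 47.2 ± 8.03 to 183 ± 27.2 CPM (log2 fold change 1.95, SE 0.15, edgeR adjusted p = 0.000108) beside Aldoc, while Ldha, a lactate dehydrogenase subunit, fell by 0.68. The other higher members, named after their values were seen, were the muscle phosphofructokinase Pfkm (0.70) and the lactate transporter Slc16a3 (1.22). Ldhd fell by 0.43, with 42.2% of its exon bases opposite Znrf1. The list's median was -0.118, its mean 0.186 and its test pointed down without passing (camera adjusted p = 0.622), and the median was above 0 with library sizes alone.

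**Figure D2:**
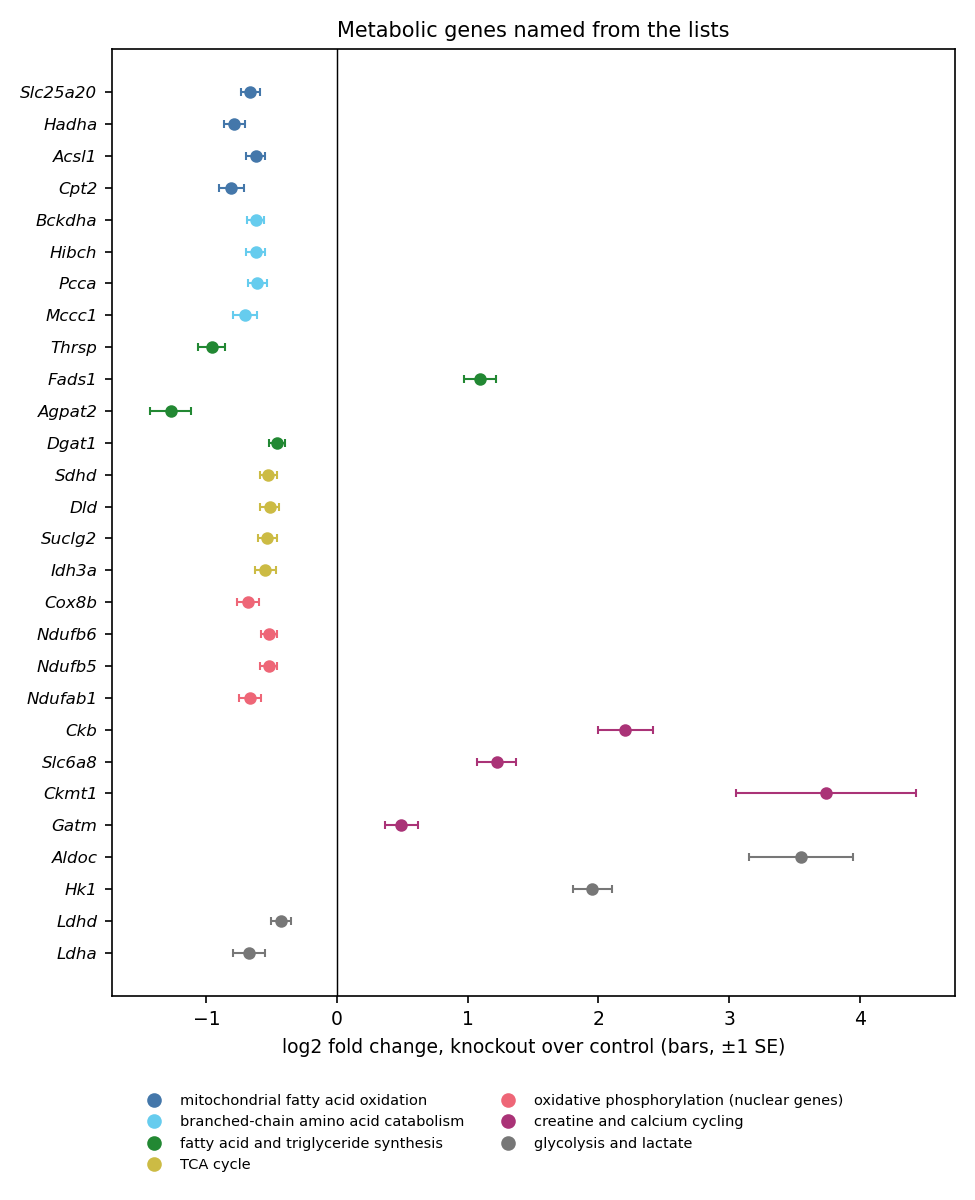
Log2 fold change, knockout over control, of 28 metabolic genes named from 7 of the fixed lists, with bars of 1 SE and 1 colour per list. Oxidation, TCA cycle and oxidative phosphorylation genes lie left of 0 and the 4 named creatine genes right of it, from Gatm (0.49) to Ckmt1 (3.74).

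Several creatine genes rose. Of 11 creatine and calcium cycling genes, 4 were higher and 0 lower, also adjusted over the list alone (median log2 fold change 1.53, camera adjusted p = 0.00694, adjusted p = 0.202 with an estimated correlation). Ckb, the brain-type creatine kinase, rose from 36.5 ± 10.6 to 168 ± 21.0 CPM (log2 fold change 2.21, SE 0.212, edgeR adjusted p = 0.00027), the creatine transporter gene Slc6a8 rose by 1.22 and the mitochondrial creatine kinase Ckmt1 rose by 3.74 from a level of 0.0687 CPM. Gatm, which makes the creatine precursor, rose by 0.49, a call that ended without knockout 515 (edgeR adjusted p = 0.0528). Among the uncalled members, named after their values were seen, were the muscle genes Atp2a1, Sln, Ryr1 and Ckmt2, with log2 fold changes of 1.53, 1.54, 1.67 and 1.83, and Gamt, which makes creatine, with -0.25. With the muscle score as a covariate the list's median was -0.0633 (camera adjusted p = 0.264), and with library sizes alone it did not pass (0.0683).

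Skeletal muscle genes, markers of a tissue that can adhere to a fat pad, had the highest median of all lists. The median log2 fold change of 20 genes was 1.56 (camera adjusted p = 0.00111, adjusted p = 0.483 with an estimated correlation), yet 2 genes were higher, 1 was lower and 0 passed when adjusted over the list alone. The list did not pass with library sizes alone (camera adjusted p = 0.0687). By edgeR the 2 higher genes were Myh2 (2.39) and Mb (2.04, with 27.6% of its exon bases opposite another gene model), and the lower was Car3, a carbonic anhydrase also abundant in fat cells (-0.60, 8005 ± 1083 CPM in controls). The calls of Myh2 and Mb ended without control 511 (edgeR adjusted p = 0.0564 and 0.0562), control 517 (0.0855 and 0.0973), knockout 512 (0.0821 and 0.0973), knockout 513 (0.0614 and 0.0822) or knockout 515 (0.0762 and 0.0678), and that of Mb also without knockout 516 (0.055). The call of Car3 ended with the covariate (0.066) and with library sizes alone (0.0694). A muscle score, the mean log2 CPM of the 19 other genes, was 7.39, 3.52, 6.77 and 7.90 in controls 511, 514, 517 and 518, and 9.35, 8.74, 8.47 and 8.14 in knockouts 512, 513, 515 and 516. The difference of 2.28 between the groups was 1.32 without control 514. Muscle actin, Acta1, named after its values were seen, stood at 62.7 CPM in control 514, 796 to 1180 in the other controls and 1720 to 3870 in knockouts. With the score as a covariate, a setting chosen after these values were seen, 1359 genes were higher and 1725 lower, and 2817 of the 4871 called genes remained called. Without control 514, 2095 genes were higher and 2435 lower.

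**Figure D3:**
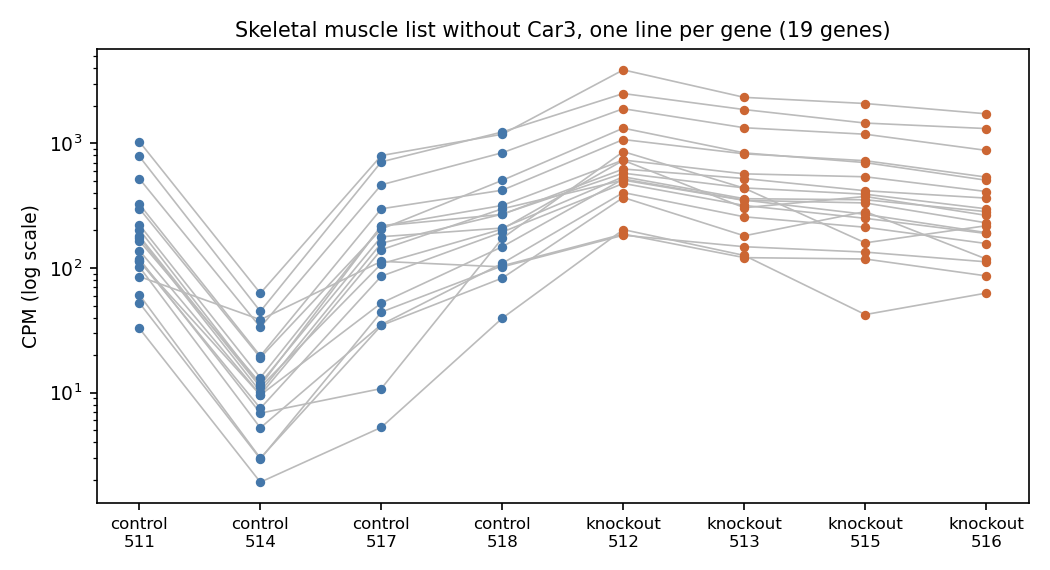
CPM (log axis) of the 19 genes of the muscle score in each library, with controls in blue, knockouts in orange and a grey line joining the points of each gene. Control 514 has the lowest value of all 8 libraries for each gene, and its Acta1 level of 62.7 CPM compares with 1720 to 3870 CPM in knockouts.

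Many matrix genes rose. Of 22 extracellular matrix and fibrosis genes 12 were higher and 0 lower, also adjusted over the list alone (median log2 fold change 0.51, camera adjusted p = 7.62e-05, adjusted p = 0.413 with an estimated correlation). The collagen cross-linking enzymes Lox and Loxl2 rose by 1.21 and 0.98, Lox from 19.6 ± 5.47 to 45.5 ± 4.99 CPM (SE 0.182, edgeR adjusted p = 0.00152), and Fbn1, fibrillin, rose by 0.69. With the muscle score as a covariate 4 matrix genes were higher. Fibroblast and preadipocyte markers had 4 of 13 genes higher and 0 lower, also adjusted over the list alone (median 0.39, camera adjusted p = 0.0127, adjusted p = 0.413 with an estimated correlation). These were Cd34 (0.83, edgeR adjusted p = 0.00228), Dlk1 (1.17), Mfap5 (0.66) and Cd248 (0.60). This list did not pass without control 514 (camera adjusted p = 0.0814), with the muscle score as a covariate (0.212) or by fry (adjusted p = 0.0524). With its score taken relative to the mean of all tested genes, 4 of the 35 splits of the libraries gave as large a difference (exact p = 0.114). Leaving out single libraries also ended the calls of Dlk1 (517 or 515, edgeR adjusted p = 0.0537 and 0.0539), Mfap5 (515 or 516, 0.0609 and 0.0575) and Cd248 (514, 517, 518, 515 or 516, 0.085, 0.077, 0.073, 0.0899 and 0.0996).

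Macrophage markers were higher in 6 of 17 cases and lower in 0, and 8 were higher adjusted over the list alone (median log2 fold change 0.63, camera adjusted p = 0.000597, adjusted p = 0.413 with an estimated correlation). Cd68, a lysosomal protein of macrophages, rose from 4.10 ± 0.602 to 7.24 ± 1.19 CPM (log2 fold change 0.82, SE 0.164, edgeR adjusted p = 0.00556). With the muscle score as a covariate 1 gene was higher and the list did not pass (camera adjusted p = 0.0776). The macrophage score, the mean centred log2 CPM of the list, was -0.0247 in knockout 512, below -0.015 in control 517, and 0.218 to 0.712 in the other knockouts. Inflammation and interferon genes were higher in 5 of 15 cases and lower in 1, also adjusted over the list alone (median 0.57, camera adjusted p = 0.00694, adjusted p = 0.413 with an estimated correlation). The score of this list was -0.0741 in knockout 512, below -0.0531 in control 517, and 0.501 to 0.563 in the other knockouts. With scores taken relative to the mean of all tested genes, 2 of the 35 splits of the libraries gave as large a difference for each of both lists (exact p = 0.0571). The chemokine genes Cxcl1, Ccl2 and Cxcl10 rose by 2.13, 2.73 and 1.496, each from 1.12 CPM or less, Tnf rose by 1.53 and the interferon regulator Irf7, named after its value was seen, rose by 0.79. With the muscle score as a covariate the calls of Ccl2 and Cxcl10 ended (edgeR adjusted p = 0.0915 and 0.052), and that of Tnf ended without control 517 or knockouts 513, 515 or 516 (0.0612, 0.0699, 0.0691 and 0.0588). The inflammation list did not pass with library sizes alone (camera adjusted p = 0.0687) or a filter on CPM (0.0547).

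Immediate early genes, which respond within minutes to stimulation or handling, were higher in 10 of 13 cases and lower in 0, and 11 were higher adjusted over the list alone (median log2 fold change 0.81, camera adjusted p = 0.000108, adjusted p = 0.202 with an estimated correlation). Fos rose from 2.16 ± 0.403 to 7.79 ± 3.40 CPM (log2 fold change 1.85, SE 0.321, edgeR adjusted p = 0.00293), the nuclear receptor gene Nr4a1 rose by 1.96 and Egr2 rose by 1.29. Cell cycle genes were higher in 3 of 12 cases and lower in 0, also adjusted over the list alone (median 0.68, camera adjusted p = 0.00729, adjusted p = 0.413 with an estimated correlation). These were the cyclin gene Ccnd1 (1.51, edgeR adjusted p = 0.00238), the proliferation marker Mki67 (1.49) and Mcm5 (0.72), whose call ended without 511, 514, 518, 513, 515 or 516 (edgeR adjusted p = 0.0553, 0.0522, 0.0584, 0.0798, 0.0906 and 0.0709). The cell cycle list did not pass by fry (adjusted p = 0.0524). Its score was -0.136 in knockout 512, below -0.055 in control 514. Taken relative to the mean of all tested genes, the score differed as much in 3 of the 35 splits (exact p = 0.0857). Of the exon bases of Ccnd1, 23.4% lie opposite a neighbouring gene.

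Stress response genes went both ways and did not pass by camera as a list (20 genes, 5 higher and 3 lower, 6 and 3 adjusted over the list alone, median log2 fold change 0.17, camera adjusted p = 0.222). The stress hormone gene Gdf15 rose by 2.99 from 0.370 ± 0.0832 CPM (SE 0.244, edgeR adjusted p = 0.000138) and Phgdh, the entry enzyme of serine synthesis, rose by 2.47, from 3.54 ± 1.90 to 19.8 ± 1.30 CPM. Hspd1, a mitochondrial chaperone gene, fell by 0.60. Glucocorticoid response genes were higher in 3 of 15 cases and lower in 1, and 3 and 0 adjusted over the list alone (median 0.52, camera adjusted p = 0.0832, and 0.0425 without control 511). Among them Hsd11b1, which regenerates active glucocorticoid, rose by 0.60 (edgeR adjusted p = 0.0124, and 0.101 with the muscle score as a covariate).

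The remaining lists did not pass by camera. Of 20 neuronal genes repressed through CoREST, a partner of LSD1, 6 passed the count filter and were tested. Of these 6, 2 were higher and 1 lower, and 3 and 1 adjusted over the list alone (median 0.25, camera adjusted p = 0.222). The sodium channel gene Scn2a1 was higher (1.14) and Rundc3a lower (-1.22). Partners and the paralog of LSD1 were lower in 4 of 18 cases and 3 adjusted over the list alone (median -0.12, above 0 with library sizes alone, camera adjusted p = 0.172). The calls of the paralog Kdm1b (-0.40), Hmg20b (-0.45), Hdac2 (-0.26) and Gse1 (-0.42) all ended with library sizes alone (edgeR adjusted p = 0.15, 0.0739, 0.589 and 0.227). Those of Hdac2 and Gse1 ended in further settings, such as without knockout 513 (0.0619 and 0.0883). Circadian clock genes were higher in 2 and lower in 2 of 16 cases, also adjusted over the list alone (median 0.20, camera adjusted p = 0.591), with Nfil3 (-1.18) and Clock (-0.67) lower and Dbp (1.27) and Ciart (1.08) higher. Without knockout 516 the edgeR adjusted p of Dbp was 0.0518 and that of Ciart 0.063, and Ciart also lost its call without 517 (0.0561) or 515 (0.0641).

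Markers of other cells in the tissue mostly had few calls. Endothelial genes were higher in 3 of 12 cases and lower in 0, also adjusted over the list alone (median 0.20, camera adjusted p = 0.222), with the junction gene Esam rising by 0.79 (edgeR adjusted p = 0.000733). Schwann cell and nerve genes were higher in 2 of 8 cases, also adjusted over the list alone (median 0.06, camera adjusted p = 0.222), the myelin protein gene Mal rising by 1.48. Smooth muscle and pericyte genes were higher in 1 of 11 cases and 0 adjusted over the list alone (median 0.14, camera adjusted p = 0.15). Lymphocyte genes had 0 of 12 calls, also adjusted over the list alone (median -0.38, camera adjusted p = 0.369, and 0.0316 without control 511). Erythroid genes had 0 of 6 calls, also adjusted over the list alone (median 0.48, camera adjusted p = 0.13, and 0.0431 without control 517). Sex-linked genes showed Y-linked transcripts in all 8 libraries and 1 to 7 counts of Xist, which is made from the inactive X chromosome. Of 4 tested sex-linked genes 1 was lower, and 2 adjusted over the list alone (median -0.239, camera adjusted p = 0.222).

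**Figure D4:**
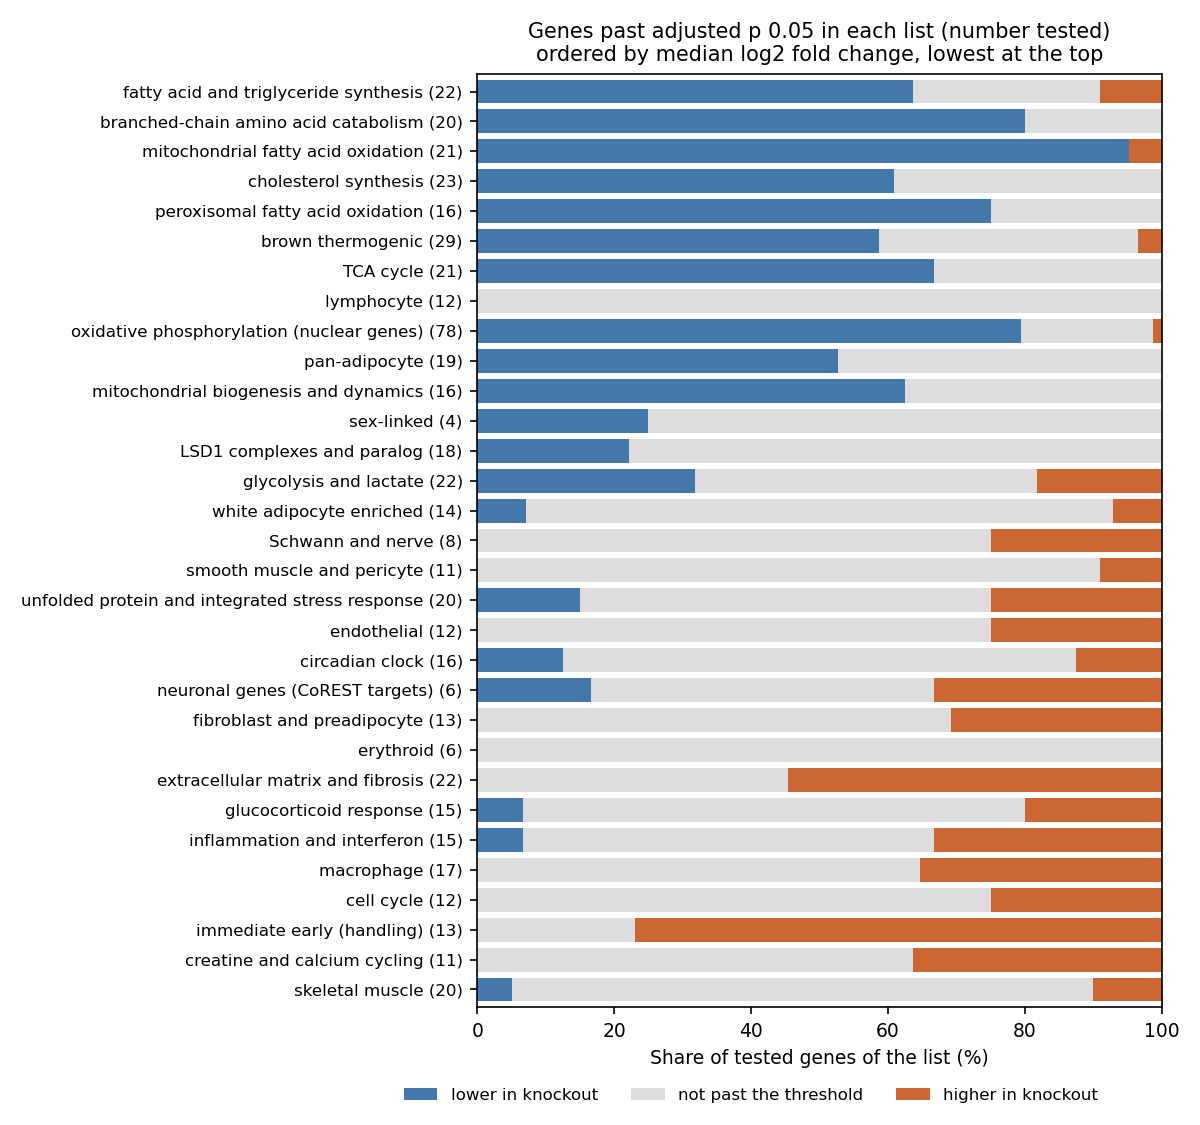
Share (%) of the tested genes of each of the 31 lists that were lower (blue), not called (grey) or higher (orange) in knockout tissue at an edgeR adjusted p under 0.05, with the number tested in brackets and lists ordered by median log2 fold change. Lists of fuel oxidation and lipid synthesis lie near the top, with 20 of 21 mitochondrial fatty acid oxidation genes lower.

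In all, 18 of the 31 tested lists passed by camera with the preset correlation, 8 higher and 10 lower, and 19 by fry. The lists differed between these tests: by fry the skeletal muscle (adjusted p = 0.099), fibroblast and cell cycle lists (0.0524 for each) did not pass, while the LSD1 complex and neuronal lists (0.0374 for each) and the stress response and Schwann cell lists (0.00825 for each) did. With an estimated correlation 0 lists passed by camera, while 6 had an unadjusted p under 0.05.

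The surroundings of Ucp1 held the clearest rise. Besides Elmod2, the neighbour on the other side of Ucp1, Tbc1d9 (chromosome 8, 83165352 to 83272940), named after its value was seen, rose from 5.09 ± 0.901 to 20.5 ± 2.35 CPM (log2 fold change 2.01, edgeR adjusted p = 8.51e-05). Farther out, Rnf150 and Scoc, also named after their values were seen, had log2 fold changes of 0.12 and 0.00337 (edgeR adjusted p = 0.333 and 0.98).

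**Figure D5:**
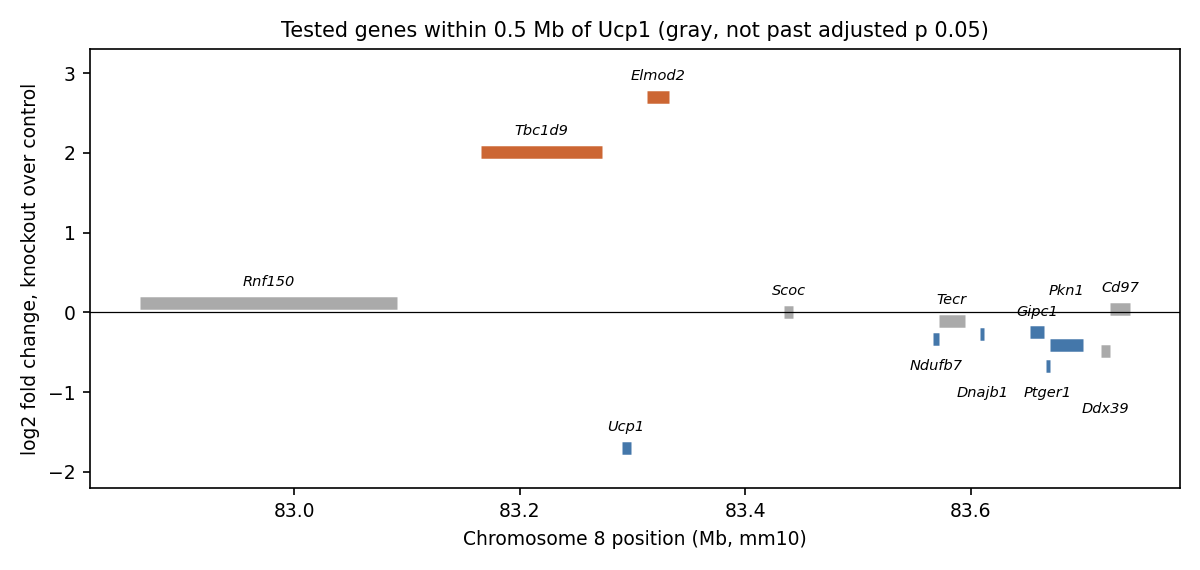
Log2 fold change, knockout over control, of the tested genes within 0.5 Mb of Ucp1, drawn to scale along chromosome 8 (mm10), with higher genes in orange, lower genes in blue and genes without a call in grey. Elmod2 (2.70) and Tbc1d9 (2.01), on either side of Ucp1 (-1.70), are the genes that rose in this window.

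The authors' deposited table gave 2835 transcripts as higher and 2487 as lower at an FDR under 0.05. Of the 4871 genes called here, 3486 (71.6%) were also called in the authors' deposited table in the same direction and 0 in the opposite one. Log2 fold changes in the authors' deposited table and here had a Spearman correlation of 0.9998 across genes, which are not independent replicates. Both come from the same libraries, so a close match says nothing about other mice. For Kdm1a and Ucp1 the authors' deposited table gave -1.45 and -1.72.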

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

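None of the tests in this part was chosen after its result was seen. In each group of 4 libraries the gap between the highest or lowest value and its nearest neighbour was divided by the whole range, and values above the 95% critical value of Dixon's test are given here. Of 350 groups checked, 16 (4.6%) stood out, and chance gives about 1 in 20.

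Among knockouts, Nr4a1, an immediate early nuclear receptor gene, was at 219 CPM in 515 and 87.7 to 101 CPM in the others (a gap of 0.842 of the range). Clstn3 was at 53.3 CPM in 516 against 45.2 to 45.7 (0.939), and Cend1 was at 44.2 CPM in 512 against 54.4 to 56.4 (0.85). Knockout 512 also had the highest Slc25a20 (455 CPM against 414 to 416, 0.953), Cox8b (645 against 613 to 617, 0.855) and Tfb2m (31.3 against 28.3 to 28.8, 0.836). Flt1, an endothelial receptor gene, was at 103 CPM in 516 against 112 to 114 (0.851).

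Among controls, Notch3, a pericyte gene, was at 82.5 CPM in 518 against 106 to 107 in the others (0.949). Control 517 had the highest Tmem221 (0.705 CPM against 0.585 to 0.603, 0.836), Dld (1490 against 1390 to 1410, 0.842) and S100b (98.7 against 79.5 to 82.1, 0.849). Ndufb6 was at 401 CPM in 514 against 364 to 370 (0.834).

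For 4 groups of list scores, the mean of its genes' log2 CPM after centring each gene, a single library also stood apart. Glycolysis was lowest in control 514 (-0.38, gap 0.906). The inflammation score was lowest in knockout 512 (-0.0741 against 0.501 to 0.563, gap 0.903). Erythroid scores were highest in control 517 (0.0798, gap 0.835) and knockout 515 (0.618, gap 0.842). Knockout 512 held 5 of the 16 values and control 517 held 4.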

How the results depend on the processing

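The muscle covariate, both length and GC corrections and the permutation of list scores were chosen after the data were seen. Of 122 called genes named by the rule, 88 kept their call and direction in all settings run with the same threshold and 34 lost the call in at least 1, most often with the muscle score as a covariate (23 genes) and without knockout 515 (20) or 516 (19). Kdm1a, Ucp1, Clstn3 and Elmod2 were among those that kept it. No called gene among those named by the rule changed direction, and with the muscle score as a covariate 4868 of all 4871 called genes had the same direction. The rule favours genes with small p-values or large changes. Of all 4871 called genes, 57.8% kept the call with the muscle covariate, 64% with library sizes alone and 69.5% without knockout 513. The number of genes depended on the scaling. Upper quartile factors gave 1625 lower genes, and library sizes alone 4077 higher and 930 lower. The TMM factors, which the last setting leaves out, were all below 1 in controls and above 1 in knockouts. With the muscle score as a covariate 1359 genes were higher and 1725 lower, with 1 residual degree of freedom fewer, and the median of the skeletal muscle list was -0.178, which follows from the construction of the score. The length and GC correction gave 2121 and 2672 genes, but 4093 lower genes without centring of the curves, a version run earlier that also shifted the median of all genes by -0.114. An adjusted p of 0.01 gave 1027 higher and 1365 lower genes, and a change of at least 1.5-fold 1511 higher and 650 lower ones, so that 69.9% of the genes were higher where 44.9% were without it. Leaving out 1 library gave 1527 to 2260 higher and 1900 to 2655 lower genes, fewest without knockout 513, and 17 to 20 lists. Where 18 lists passed with the planned test, 15 did with library sizes alone, 14 with the muscle covariate, 19 by fry, 0 with an estimated correlation (6 at an unadjusted p under 0.05) and 0 in the exact permutation. In that permutation 17 lists had the smallest p the 35 splits can give, 0.0286, and the lowest adjusted value was 0.0521 because the other lists had larger p-values. The overlap with the deposited edgeR table of the authors was 80.2% for the edgeR exact test without a low-count filter. The counts and directions of the other settings stayed within 1.5 times, for example 2108 higher genes without a low-count filter, 2545 with DESeq2, and 2963 higher and 3699 lower transcripts when each transcript was tested. No paired analysis was possible because the groups share no replicate number. In simulated data at this depth, with far fewer changed genes than here, 22% of genes changed 1.5-fold and 62% of those changed 2-fold were found.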

Other observations

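The tests of the muscle genes' correlation, of the adipocyte genes and scores and of the scaling, the test of distant neighbours of Ucp1, the muscle covariate and length corrections, the permutation of list scores and the gene families below were chosen after the results they bear on were seen.

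Among gene families that were lower were those of mitochondrial protein synthesis and import. Grouped by the stem of the symbol, 45 of 48 Mrpl genes and 26 of 29 Mrps genes, which encode mitochondrial ribosomal proteins, were lower, with 0 higher (medians -0.45 and -0.48, camera adjusted p = 2.82e-16 and 5.04e-10, adjusted p = 0.339 with an estimated correlation for each). Genes with the stems of import proteins were lower in 11 of 13 Timm and 9 of 11 Tomm cases (medians -0.55 and -0.52, camera adjusted p = 1.05e-05 and 0.00057, adjusted p = 0.339 with an estimated correlation for each). The Tomm count includes Tomm6os, a transcript opposite Tomm6 that counting without strand could not separate from it. With library sizes alone these 4 families had 30, 15, 9 and 8 lower genes (medians -0.251, -0.284, -0.358 and -0.324) and 1 higher Tomm gene, and with the muscle score as a covariate 36, 17, 10 and 7 lower genes. Peroxin genes (Pex), which build peroxisomes, were lower in 9 of 16 cases (median -0.345, camera adjusted p = 0.000898, adjusted p = 0.339 with an estimated correlation), in 6 with library sizes alone and in 8 with the covariate. Genes with the stem Eif, mostly translation initiation factors but also kinases such as Eif2ak3 and repressors such as Eif4ebp1, were lower in 28 of 52 cases and higher in 3 (median -0.246, camera adjusted p = 7.73e-05, adjusted p = 0.339 with an estimated correlation). Of the Eif genes 7 were lower and 3 higher with library sizes alone (median -0.0507), and with the covariate 17 were lower and 2 higher. Of 212 such families 30 passed by camera, 8 higher and 22 lower, and 117 by fry. With an estimated correlation 0 passed by camera, while 25 had an unadjusted p under 0.05. The lower families also included others such as Vps (15 of 32 lower, camera adjusted p = 0.0102, adjusted p = 0.358 with an estimated correlation), which depended on the scaling, with 3 lower and 4 higher and a median of 0.0145 with library sizes alone.

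Among the families that were higher were Fgf, Adamts, Bmp and Asb. Of 11 Fgf genes, which encode fibroblast growth factors, 6 were higher and 0 lower (median 0.73, camera adjusted p = 0.041, adjusted p = 0.339 with an estimated correlation), and 3 were higher with the muscle score as a covariate. Among them were Fgf9 (2.02), Fgf18 (1.47) and Fgf1, which rose from 39.0 to 66.8 CPM. Of 15 Adamts genes, which encode matrix proteases, 5 were higher and 0 lower (median 0.64, camera adjusted p = 0.0258, adjusted p = 0.5 with an estimated correlation), also 5 with the covariate. Genes with the stem Bmp are those of bone morphogenetic proteins, except for the kinase gene Bmp2k and the protease gene Bmp1. They were higher in 4 of 9 cases, Bmp1 (0.43) among them, and in 2 with the covariate (median 0.50, camera adjusted p = 0.0429, adjusted p = 0.458 with an estimated correlation). Bmp8b rose by 3.79 from 0.388 CPM (edgeR adjusted p = 0.000796). Asb genes were higher in 9 of 16 cases and lower in 1, Asb8 (-0.27, edgeR adjusted p = 0.0108), with a median of 1.07 (camera adjusted p = 0.0146, adjusted p = 0.561 with an estimated correlation), but higher in 1 case with the covariate (median 0.173). The medians of Fgf, Adamts, Bmp and Asb kept their sign with each scaling.

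Other divisions of the 8 libraries into 4 and 4 were tested in the same way. For genes, the real division gave 4871 and the highest of the others 2, so that 1 of 35 divisions gave as many. The smallest exact p that 35 divisions can give is 0.0286, so this count alone does not exclude chance. The other divisions mix the groups, which adds the real difference to the spread within each and lowers their counts. For lists, 7 of 35 divisions gave at least 18 lists, the highest of the others 22. Divisions that exchange 1 library keep part of the real difference between the groups. This count therefore cannot settle whether chance gave the number of lists. The 16 divisions that exchange 1 library between the groups gave 10 to 22 lists, 6 of them as many as the real one, and the 18 that exchange 2 gave 1 to 11.

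The higher skeletal muscle genes may come from varying amounts of attached muscle. If so, the muscle genes should move in a fixed ratio within the controls, and their median pairwise correlation over the controls was 0.985 (0.87 without control 514, and 0.971 within knockouts). With the muscle score as a covariate 96.4% of the called genes kept their direction and at least 0.5 of their estimate. The share that remained called was 57.8%. The score was higher in each knockout than in each control, so its slope rests on the spread within the groups. There control 514 stood apart (3.52, beside 6.77 to 7.90 in the other controls). The kept estimates argue against muscle as the whole cause of the calls only as far as that slope is right. A rise of muscle genes within knockout brown adipocytes was not tested and stays open, because no library was measured apart from the tissue.

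Among the lower metabolic genes, Ucp1 fell further than Adipoq, Plin1 and Plin4, uncalled genes picked after their values were seen, by at least 1.49 on the log2 scale (SE 0.207). That argues against a lower share of all fat cells as the whole cause for Ucp1 only as far as these genes measure that share. Of the 19 pan-adipocyte genes 10 were lower, such as Cidec (-0.9965) and Mgll (-0.88), and 9 had no call. A lower share of brown cells among the fat cells cannot be judged from genes that all fat cells share. For the metabolic lists together a lower share of adipocytes stays open. Their score fell further than that of the pan-adipocyte list by a difference of -0.0679 (SE 0.0337), or -2.02 standard errors. This is past a bound of 2 tried earlier but within the t quantile of 2.45 for these libraries. A correction for length and GC was run with the TMM scaling kept, and not together with another scaling. Under TMM scaling, length or GC bias as the whole cause is argued against for the oxidative phosphorylation list. Its median after the correction was -0.251, with 45 of 78 genes lower. Scaling stays open in the same way, as this median was -0.151 with library sizes alone and the list's score differed by -0.0896 (SE 0.0382), or -2.34 standard errors, also past the bound of 2. A criterion set earlier, the median relative to all genes, was dropped because scaling moves all genes alike and cannot change it. A lower activity of this programme in Lsd1-deficient brown adipocytes and an effect of the Cre transgene, carried by all knockout mice and no control, may each contribute and were not separated.

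Elmod2 and Tbc1d9 flank Ucp1, whose promoter drives Cre, and their rise may come from copies of genes carried with the transgene. Genes farther away do not decide this. The median of 47 genes 0.5 to 2 Mb from Ucp1 was -0.0888, beside -0.012 for all genes, so they showed no shared rise. That would also hold if the loss of Lsd1 raised only Elmod2 and Tbc1d9. The criterion further asked that none of the 47 be called, which could hardly be met where 34.4% of all tested genes were called. Of the 47, 15 were called, in both directions. A shifted chromosome region, at an insertion site or from another strain, was also looked for in windows of 20 neighbouring genes. The largest mean z was 2.55 (95th percentile of shuffled orders 2.18), in a single region on chromosome X, 134686519 to 136837742, where 13 of 20 genes were higher, many of them related genes such as Armcx1 and Armcx2. This region holds neither Elmod2 nor Tbc1d9, so its shift does not by itself explain their rise. Regulation of Elmod2 and Tbc1d9 through the loss of Lsd1 also stays open, and reads over the transgene's junctions, not analysed here, would be needed to separate these.

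Rises lay mostly among weakly expressed genes. LSD1 is part of repressor complexes, so a release of silent genes in its absence is a hypothesis, which predicts more rises than falls in the lowest of 4 equal groups of genes by mean expression. There 787 genes were higher and 100 lower, so that 88.7% of the calls were higher, and in the highest group 214 were higher and 1450 lower. With the muscle covariate these counts were 434 and 72 in the lowest group and 154 and 964 in the highest. With library sizes alone they were 1162 and 53 in the lowest and 607 and 550 in the highest, so the excess of falls among highly expressed genes depends on the scaling. The groups of genes were formed by the mean over all 8 libraries, knockouts included. The counts restate the pattern and do not tell a release of silent genes from other causes of the rises.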
